A study of Ovis aries with 18 samples.

How the data were processed

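RNA from 3 skeletal muscles of lambs was measured by sequencing, with 6 libraries per muscle and 18 in all. The muscles were soleus (SOL), longissimus lumborum (LL) and psoas major (PM). Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was depleted, and cDNA was made with random hexamers. The protocols state that reads were trimmed, aligned to the sheep genome with HISAT2 (2.2.1) and assembled with StringTie (2.2.0), and that transcripts without coding potential were kept as long non-coding RNAs. The submitters' processing notes name DESeq without a role. The genome build, the annotation version, the counting program and the strand setting are not given in the sources used here.

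The deposited table holds 20477 rows and 1 column per library. Its name refers to lncRNA, but every row carries an Ensembl sheep gene identifier and no row carries an assembled transcript. The file header names no unit. Tested on its values, the table holds FPKM as deposited by the authors, that is reads per kilobase of gene and per 1000000 counted reads. Each positive value came within 0.05 of a whole number of reads when multiplied by a whole gene length and by 1 library total, and the 18 library totals fell within 5.2e-05 of whole numbers. Reads, gene lengths and library totals were therefore recovered from the values. On simulated data of 5892 genes, the same procedure returned all reads of 99.9% of genes exactly. Of 13990 genes detected in 12 or more libraries, 50.9% had a length divisible by 3, where lengths unrelated to codons would give 33.3%. The rows are therefore called genes here, and no statement is made on whether a row is non-coding. A separate table of assembled lncRNAs was not analysed here.

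The identifiers could not be paired with names: 0 of them matched the RefSeq gene table used, which lists no Ensembl identifiers, and the deposited table gives no names or positions. The 17 gene lists fixed before the data were examined (fibre type, metabolism, patterning, other cell types and known lncRNAs among them) therefore had no members and were not tested. For the same reason the rule for named genes, also set before the data were examined, allowed only 2 identifiers each way per comparison. These were the largest log2 fold changes among genes with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 0.5 FPKM and no overlap between the 2 muscles. Coordinates are not given.

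Because the table holds normalized values, the test planned for counts was not used. Genes with a mean of at least 0.1 FPKM over all libraries were tested (15434 genes) as log2(FPKM + 0.1) with limma (3.58.1, R 4.3.3), with the variance trend, 1 coefficient per muscle, 15 residual degrees of freedom and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, two-sided. Fold changes are on the log2(FPKM + 0.1) scale, which understates changes of low genes. Comparisons of 1 value per library used exact two-sided permutation tests in scipy (1.17.1). In simulated data with 200 changed genes, a log2 change of 2 in genes with a mean of at least 10 FPKM was recovered in 97.8% of cases for SOL against LL, 94.9% for SOL against PM and 98.0% for PM against LL. Among all changed genes tested in SOL against LL, 69% with a log2 change of 2 and 37% with a log2 change of 1 were recovered. Calls of unchanged genes in these simulations numbered 5 of 111 for SOL against LL, 5 of 119 for SOL against PM and 13 of 127 for PM against LL. Each simulated gene had the same spread in all muscles and the libraries were independent. These rates therefore do not cover muscles that differ in spread, or paired libraries.

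The labels number the libraries 1 to 6 in each muscle, and the series' design text states that the muscles were taken from each carcass without tying a number to a carcass. The main model had no block. Deviations from the muscle means correlated across genes between all 6 same-numbered SOL and PM libraries (r from 0.13 to 0.23, all above 0.1). The numbers were therefore taken to pair these libraries, and the blocked model was run as an alternative. The LL libraries did not meet this rule for all numbers. Their lowest same-numbered r was 0.090 with PM and 0.086 with SOL. The highest r between different numbers was 0.0070 with PM and 0.052 with SOL. Every same-numbered r thus exceeded every other, so the numbers likely pair the LL libraries too. Other alternatives were other pseudocounts and filters, a fold threshold, fits on 2 muscles, and leaving out each library. Chosen after seeing the data were median-ratio scaling, limma's voom on the recovered reads, library quality weights, a filter of 10 FPKM and leaving out 3 libraries together. Where numbers do not identify animals, p-values measure the spread between these libraries.

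Library totals ranged from 10216739 to 14747118 reads. In a library of the mean total, 12415881 reads, 1 read on a gene of 1 kb is worth less than 0.1 FPKM. Floors of 3 reads and intervals cover counting error only, since no molecular identifiers are described.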

Results

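The transcriptomes of 3 sheep skeletal muscles were compared: longissimus lumborum (LL), a long muscle of the loin; psoas major (PM), the tenderloin muscle; and soleus (SOL), a postural muscle of the hind leg. Each muscle was represented by 6 libraries. The table listed 20477 genes, of which 17448 had a value above 0 in at least 1 library and 15434 were tested. Library totals were 11807281 ± 987089 reads in LL, 12353219 ± 923615 in PM and 13087142 ± 990250 in SOL (SD, n = 6 each). Genes are given by Ensembl identifier, since the table does not pair them with names.

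Fewer genes were detected in LL than in the other muscles. At least 1 read was found for 13733 ± 653 genes in LL, 14804 ± 110 in PM and 15006 ± 432 in SOL (SD, n = 6 each). The difference of 1070 genes between PM and LL had an exact permutation p of 0.0022 (0.0065 after adjustment over 3 comparisons), and each PM library exceeded each LL library. The difference of 1272 genes between SOL and LL had an exact permutation p of 0.0065 (0.0097 adjusted). Both tests ignored the replicate numbers, which likely pair the LL libraries too. A sign-flip test on 6 pairs cannot give a p under 0.031, and none was run for the differences from LL. SOL and PM differed by 202 genes, which was not larger than the spread between libraries (exact permutation p = 0.31), with SOL higher in 5 of 6 same-numbered pairs (exact sign-flip permutation p = 0.25). This rested on SOL 5, at 14181 genes: without it the difference was 366.9 genes (exact permutation p = 0.0043), and each of the other 5 SOL libraries exceeded each PM library. SOL 5 was left out after the counts were seen. The permutation test without SOL 5 ignored the numbered pairs, and a paired test without it was not run. The pairs left are too few for a sign-flip test to reach a p under 0.05, so a paired test could not have passed. LL libraries resembled each other less: the mean correlation of a library with the others of its muscle was 0.87 to 0.90 in LL, 0.93 to 0.94 in PM and 0.92 to 0.93 in SOL. Whether this only restates the smaller number of genes detected was not tested. For genes with 1000 to 10000 reads, the median absolute log2 deviation was 0.226 in LL, 0.179 in PM and 0.192 in SOL. Neither PM nor SOL differed from LL there (exact permutation p = 0.071 and 0.24).

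**Figure D1:**
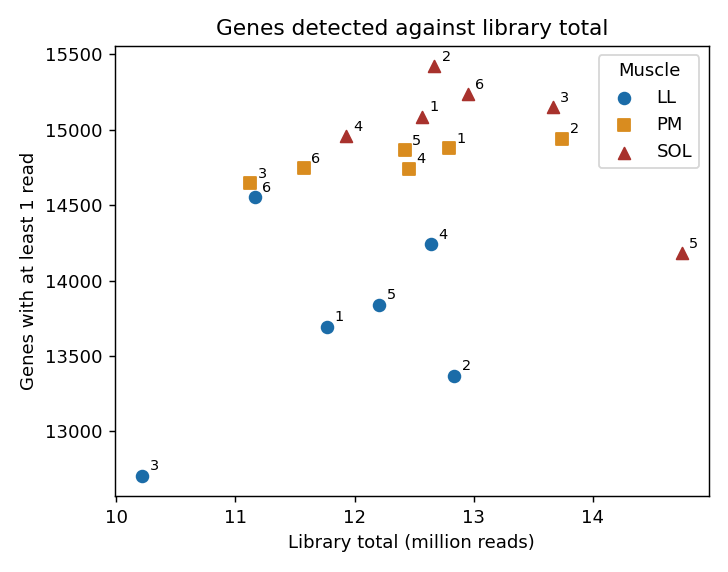
Number of genes with at least 1 read (vertical axis) against the library total (horizontal axis, reads in units of 1e+06), with 1 point per library, numbered by replicate. The 6 LL libraries lie between 12704 and 14552 genes, and the 6 PM libraries lie between 14647 and 14942.

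SOL separated from both other muscles along the main axis of variation. The first principal component held 24.7% of the variance, with scores of 72.8 ± 14.9 in SOL, -17.6 ± 14.9 in PM and -55.3 ± 23.7 in LL (SD, n = 6 each). SOL scores began at 59.2, above the highest PM score of 3.86. LL and PM scores overlapped. One library, LL 3, lay apart on the second component (10.5% of the variance) at -131.7. In limma's F-test, 3604 of 15434 genes differed among the 3 muscles at an adjusted p under 0.05. With the replicate block the count was 4202.

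**Figure D2:**
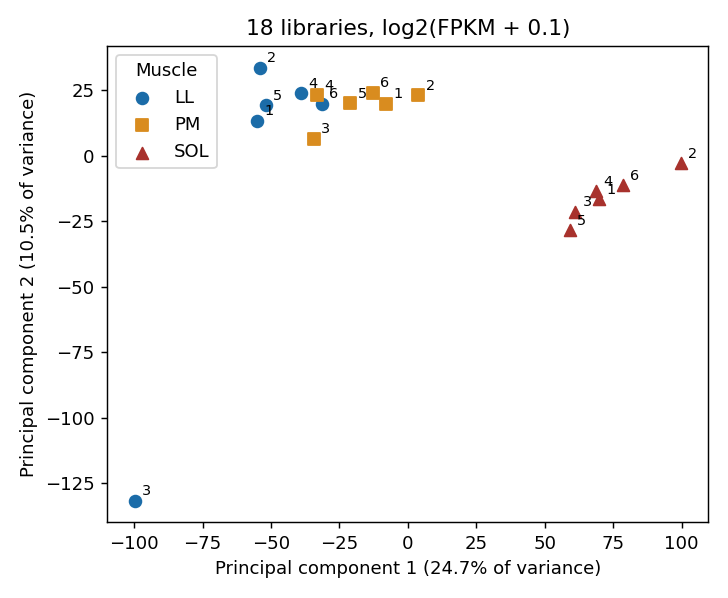
Scores of the 18 libraries on the first and second principal components of log2(FPKM + 0.1) over 15434 genes, numbered by replicate; both axes give the share of variance. SOL lies to the right of the others, and LL 3 stands apart at the bottom.

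SOL was compared with LL to find the genes whose level differs between these muscles. In SOL, 2632 genes were higher and 1283 lower, together 3915 genes or 25.4% of those tested (limma, adjusted p under 0.05). Of these, 2107 differed by at least 1 on the log2 scale, and 280 by at least 3. The abundant transcripts differed strongly: of the 140 genes that were among the 100 most abundant of either muscle, 91 were called, 47 higher and 44 lower in SOL, and 43 of them differed by a log2 change of 2 or more. Only 60 genes belonged to the 100 most abundant of both.

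The genes with the largest falls went from among the most abundant of LL to nearly none in SOL. ENSOARG00020018635 (recovered length 5935 bp) stood at 6241 ± 905 FPKM in LL and 25.7 ± 55.5 in SOL (SD, n = 6 each), with a log2 fold change of -10.21 (SE 0.71, limma adjusted p = 1.4e-09). In SOL it ranged from 1.73 to 7.47 FPKM in 5 libraries and was 139 in SOL 3. ENSOARG00020016724 (3541 bp) fell from 1766 ± 177 to 5.77 ± 12.4 FPKM, with a log2 fold change of -10.25 (SE 0.66, limma adjusted p = 5.1e-10), and SOL 3 was again the highest SOL library at 31.1 FPKM. Without SOL 3 the log2 fold changes were -11.16 and -11.14. Among genes higher in SOL, ENSOARG00020004162 (1080 bp) stood at 51.8 ± 9.75 FPKM in SOL and 0.151 ± 0.288 in LL, where 3 libraries had no read (log2 fold change 8.19, SE 0.55, limma adjusted p = 8.3e-10). ENSOARG00020023156 (1340 bp) stood at 15.4 ± 6.34 FPKM in SOL and had reads in only 1 LL library, LL 6, at 0.468 FPKM (log2 fold change 6.74, SE 0.64, limma adjusted p = 1.0e-07). The size of these rises depended on the pseudocount. With a pseudocount of 1 the log2 fold changes were 5.5 for ENSOARG00020004162 and 3.8 for ENSOARG00020023156, and with 0.01 they were 10.2 and 9.5.

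The split of calls depended on level and on scaling. Genes with a mean of 0.1 to 1 FPKM were called in 11.6% of cases, 309 higher and 24 lower in SOL, while those at 100 FPKM or more were called in 57.0% of cases, 182 higher and 200 lower. After median-ratio scaling these numbers were 275 and 27 at 0.1 to 1 FPKM, and 145 and 229 at 100 FPKM or more. LL, the muscle with fewer genes detected, is one side of this comparison. SOL against PM, however, also leaned to higher calls at 0.1 to 1 FPKM, with 134 higher and 24 lower, and 109 and 28 after scaling. For SOL against LL, 67.2% of calls over all levels were higher in SOL as deposited and 54.9% after median-ratio scaling, which lowered the median log2 fold change of all tested genes from 0.24 to 0.13. Of the 3915 calls, 3376 were also called after that scaling. Every library of one muscle lay beyond every library of the other for 1761 genes, where chance gives 0.216% or about 33 genes.

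SOL was compared with PM in the same way. In SOL, 1698 genes were higher and 899 lower, together 2597 or 16.8% of those tested (limma, adjusted p under 0.05), and 158 differed by at least 3 on the log2 scale. These counts are from the model without a block. With the replicate block, which takes the numbered pairs into account, 2012 genes were higher and 1051 lower in SOL, together 3063. In fits on only the 12 libraries compared, SOL against PM gave 3233 calls and SOL against LL 3264. The smaller count for SOL against PM thus did not hold in those fits. Of the 134 genes among the 100 most abundant of either muscle, 82 were called, 46 higher and 36 lower in SOL. Of the genes under the rule for naming, ENSOARG00020018635 had the largest fall here, from 5795 ± 1041 FPKM in PM (log2 fold change -10.10, SE 0.71, limma adjusted p = 3.2e-09). ENSOARG00020018538 (6051 bp) fell from 2273 ± 540 FPKM in PM to 18.4 ± 41.3 in SOL (log2 fold change -9.57, SE 0.77, limma adjusted p = 1.7e-08); SOL 3 held 103 FPKM and the other SOL libraries 0.778 to 2.90, and without SOL 3 the log2 fold change was -10.60.

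The largest rise in SOL against PM was that of ENSOARG00020023900 (774 bp), from 1.5 ± 0.83 FPKM in PM to 998 ± 574 in SOL (log2 fold change 9.16, SE 0.49, limma adjusted p = 6.4e-11). Its level in LL was 9.71 ± 6.53 FPKM, higher than in PM (log2 fold change of PM against LL -2.48, limma adjusted p = 0.011). ENSOARG00020009813 (1536 bp) rose from 1.38 ± 1.27 to 102 ± 19.9 FPKM (log2 fold change 6.62, SE 0.53, limma adjusted p = 1.8e-08). Of the SOL against PM calls, 65.4% were higher in SOL as deposited. After median-ratio scaling, 1260 genes were higher and 1262 lower in SOL, an even split. Groups did not overlap for 1626 genes, against about 33 by chance.

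**Figure D3:**
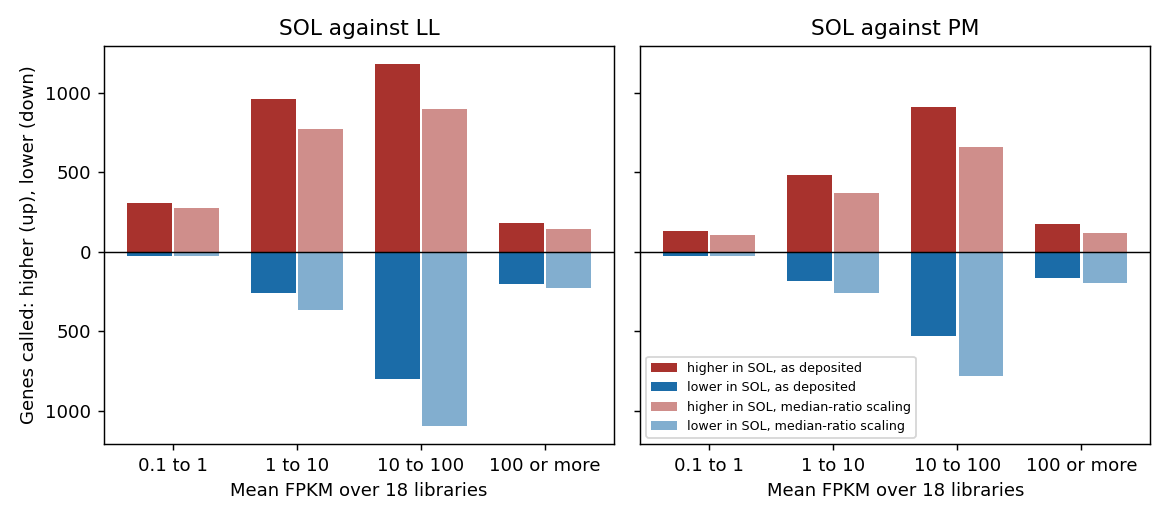
Genes called (limma, adjusted p under 0.05) as higher in SOL (bars above 0) or lower in SOL (bars below 0), by mean FPKM over the 18 libraries, for SOL against LL and SOL against PM; dark bars use FPKM as deposited and pale bars median-ratio scaling. At 0.1 to 1 FPKM nearly all calls of SOL against LL were higher in SOL (309 and 24), and at 100 FPKM or more 182 were higher and 200 lower as deposited, against 145 and 229 after scaling. For SOL against PM the bin of 0.1 to 1 FPKM held 134 and 24 as deposited, and 109 and 28 after scaling. The bin of 100 FPKM or more held 174 and 166 as deposited, and 119 and 195 after scaling.

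A common set of genes set SOL apart from both other muscles. In the same direction in both comparisons, 2115 genes were called, 1371 higher and 744 lower in SOL, and 3 genes were called in opposite directions. After median-ratio scaling 1038 were higher and 1040 lower, an even split. The replicate block gave 1643 higher and 871 lower. Independent lists of the sizes in the main fit would share about 290 higher and 74.7 lower genes. Both comparisons use the same SOL libraries. At an unadjusted p under 0.05 (limma), 3438 genes were shared in the same direction, against a mean of 166 and at most 203 in 100 simulations of unchanged muscles with shared SOL libraries. No gene differed between muscles in these simulations, so they cannot gauge the sharing that common SOL libraries add where SOL does differ. At an adjusted p under 0.05 these simulations shared 0 genes, as the adjustment leaves almost no calls where nothing changes. With SOL split into separate sets of 3 libraries, 1 set for each comparison, 1049 and 1041 genes were shared, against 92.2 and 91.0 higher and 33.0 and 29.7 lower for independent lists.

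PM and LL differed in far fewer genes. In PM, 144 genes were higher and 85 lower, together 229 or 1.48% of those tested (limma, adjusted p under 0.05), and 21 differed by at least 3 on the log2 scale. A fit on only the 12 libraries of PM and LL gave 131 calls, 74 higher and 57 lower. The replicate block gave 415 calls, 257 higher and 158 lower. The numbers were not taken as pairs for LL, but pairing is likely, so the lower count without the block is not settled. The counts also rested on single libraries: the total was 150 without PM 1, 138 without PM 2, 150 without PM 4 and 149 without PM 6, and rose to 340 without LL 6. The lower calls numbered 54 without LL 5, 151 without LL 6, 56 without PM 1, 51 without PM 2, 53 without PM 4 and 52 without PM 6, and the higher calls 94 without PM 1 and 87 without PM 2. Of the 100 most abundant genes of each muscle, 84 were shared, and 14 of the 116 in either set were called, 10 higher and 4 lower in PM. ENSOARG00020004175 (1062 bp) had no read in any LL library and 10.9 ± 7.85 FPKM in PM, at least 45.1-fold higher than a floor of 3 reads per LL library (limma adjusted p = 2.3e-08); SOL held 1.32 ± 0.678 FPKM. ENSOARG00020004162, which was higher in SOL than in LL, was also higher in PM (12.2 ± 9.98 FPKM) than in LL (log2 fold change 5.65, SE 0.55, limma adjusted p = 6.4e-06), and SOL exceeded PM (log2 fold change 2.54, limma adjusted p = 0.0025). For PM against LL its log2 fold change was 3.2 with a pseudocount of 1 and 7.6 with 0.01.

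In the other direction, ENSOARG00020005847 (1401 bp) stood at 30.4 ± 9.10 FPKM in LL with 3047 reads over 6 libraries and had 1 read over the 6 PM libraries. The ratio of LL to PM per library total was 3188, with an exact 95% counting interval of 572 to 125956 (limma adjusted p = 7.9e-11). Its level in SOL was 0.0557 ± 0.0926 FPKM, with 4 libraries at 0. ENSOARG00020013617 (3466 bp) stood at 103 ± 37.1 FPKM in LL and 2.53 ± 1.95 in PM (log2 fold change -5.61, SE 0.44, limma adjusted p = 1.8e-07), and at 2.66 ± 1.51 in SOL, so both genes were lower in SOL than in LL as well (log2 fold changes -7.73 and -5.29). Groups did not overlap for 205 genes, against about 33 by chance.

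**Figure D4:**
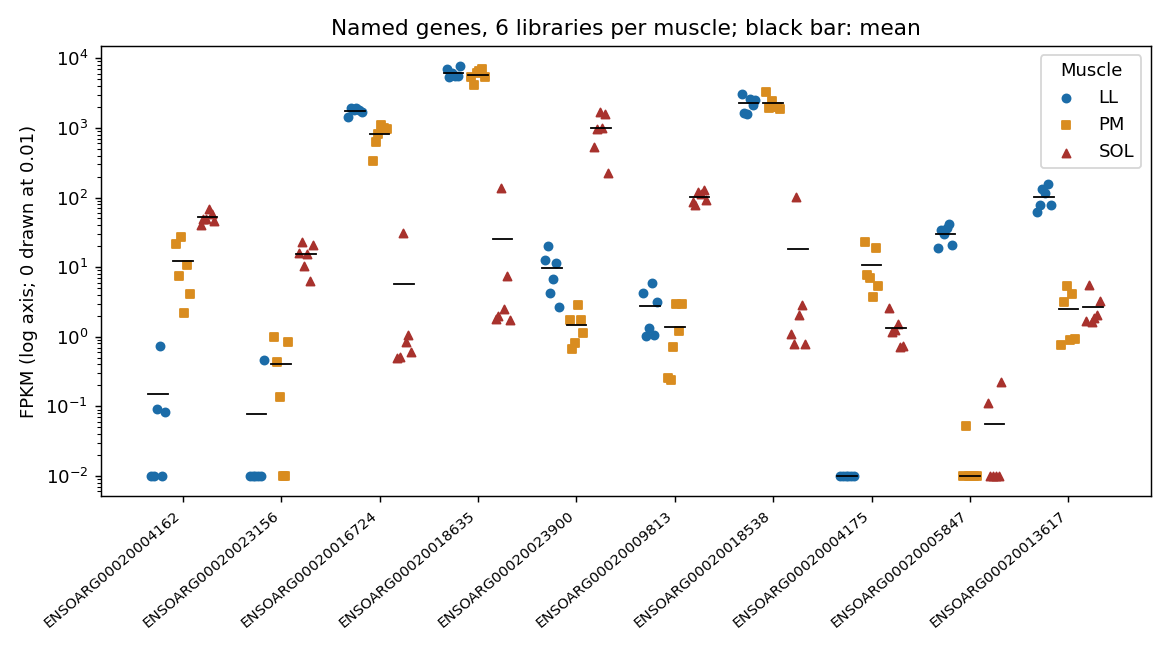
FPKM (log axis, values of 0 drawn at 0.01) of the 10 named genes in each of the 6 libraries per muscle, with a black bar at the mean. ENSOARG00020018635 and ENSOARG00020018538 lie above 1000 FPKM in all LL and PM libraries, and SOL 3 is the highest SOL library for both.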

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

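All tests of explanations in this part were chosen after the results were seen, and 2 of them replaced tests tried earlier, as given with each. In each muscle the highest and lowest of 6 libraries were compared with the rest (Dixon's test) for 5 library measures and for the named genes. Of 45 sets tested, 9 stood out. Chance would give about 2.25 for normally distributed values. That figure does not apply to FPKM near the floor, where a single library with reads among libraries with none always stands out.

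In SOL 3, transcripts that were nearly absent from the other soleus libraries appeared: ENSOARG00020018635 stood at 139 FPKM against 7.47 or less, ENSOARG00020018538 at 103 against 2.90 or less, and ENSOARG00020016724 at 31.1 against 1.07 or less. Of the 11 genes that reached at least 10 FPKM in LL and PM and stayed under 1% of that level in the other 5 soleus libraries, all 11 exceeded 1% in SOL 3, with an excess of 1.73% to 4.45% (median 2.52%). LL or PM RNA mixed into this library may be the source. With PM 3 as the only donor, the log2 share needed per gene had an SD of 0.385. That lies within the range of 0.238 to 0.635 between an LL or PM library and its closest fellow. LL 1 came almost as close (0.392), and further libraries of both muscles also fell within that range. ENSOARG00020005847, the only gene at 10 FPKM or more in LL, under 10% of that in PM and under 1% of it in the other 5 soleus libraries, had 0 reads in SOL 3. An LL donor at its median share would bring 7.61 to 19.2 reads, which goes against an LL donor but rests on 1 gene, and 0 genes met the same rule for PM. The test on all 11 genes replaced an earlier one on the ratio of only the 2 most abundant of them, which had also gone with mixing. Neither test can tell mixing from a soleus that made these transcripts in proportions like those of LL or PM, since both would give similar shares. That this soleus itself made these transcripts was not tested and stays open.

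SOL 5 had the fewest genes detected in its muscle, 14181 against 14959 or more, and 149 genes with 1 read against 371 or more. LL had the same traits as a muscle. Depth and a few abundant genes do not account for it: PM still exceeded LL by 1030 genes after thinning every library to 10216631 reads, and by 1039 genes after removing the 100 most abundant genes and thinning. Whether LL reads came from fewer distinct molecules cannot be told apart from a difference between the muscles themselves. The first measure tried, the variance over the mean of genes with 5 to 20 reads, was 17.7 in LL and 23.4 in PM (exact permutation p = 1, n = 6 each), where PM 2 alone stood at 105, the other PM libraries at 5.16 to 9.05 and LL at 12.4 to 29.6. The measure put in its place after that outcome was the share with no read among genes with 5 to 20 reads in the other libraries of the muscle, at 15.0% to 53.0% in LL, 8.23% to 12.6% in PM and 29.5% in SOL 5, a difference in means of 21.9 percentage points between LL and PM. It ranked the libraries of each muscle exactly as the number of genes detected did, so that it restates the pattern, and the scatter of genes with 1000 to 10000 reads, 1.26 times as large in LL as in PM, did not pass (exact permutation p = 0.071).

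ENSOARG00020004162 stood at 0.732 FPKM in LL 4 against 0.0906 or less in the other LL libraries. ENSOARG00020023156 stood at 0.468 FPKM in LL 6 and at 0 in the other LL libraries. ENSOARG00020005847 stood at 0.0519 FPKM in PM 2, which is 1 read, and at 0 in the other PM libraries. ENSOARG00020018538 stood at 3313 FPKM in PM 1 against 2410 or less in the other PM libraries.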

How the results depend on the processing

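The counts of genes differing among muscles, of SOL against LL, of SOL against PM and of genes setting SOL apart stayed within 1.5 times of the reported values under the replicate block, other pseudocounts, no low-value filter, a filter of 1 FPKM and each left-out library, and, among alternatives chosen after seeing the data, under median-ratio scaling, voom on recovered reads, quality weights and leaving out LL 3, SOL 3 and SOL 5 together. With an absolute log2 fold change of at least 1 required, which only removes calls, 2035 genes differed among muscles; SOL against LL gave 2107 (1547 higher, 560 lower), SOL against PM 1297 (874 and 423), genes setting SOL apart 1048 (702 and 346) and PM against LL 124 (86 and 38). A filter of 10 FPKM, which tests fewer genes, gave 2561 for SOL against LL, 1481 of them higher. With only the 12 libraries compared, PM against LL gave 131, 74 of them higher. SOL against LL then gave 3264 and SOL against PM 3233, where the main fit gave 3915 and 2597. Quality weights gave 3697 and 3543. The gap between these 2 comparisons in the main fit was thus small or nearly absent in those fits, and the cause was not tested. Leaving out 1 library moved PM against LL between 138 and 340 in total, 87 and 189 higher, and 51 and 151 lower. The total was 150 without PM 1, 138 without PM 2, 150 without PM 4 and 149 without PM 6; the higher calls were 94 without PM 1 and 87 without PM 2; and the lower calls were 54 without LL 5, 151 without LL 6, 56 without PM 1, 51 without PM 2, 53 without PM 4 and 52 without PM 6. The replicate block raised PM against LL to 415 (257 higher, 158 lower) and left the other counts within 1.5 times, at 3063 for SOL against PM and 4543 for SOL against LL; it changed the call of none of the 12 named results, and the cause of the rise was not tested. For LL the numbers were not taken as pairs: same-numbered r exceeded 0.1 in 4 of 6 cases with SOL and 5 of 6 with PM. Every same-numbered r still exceeded every other, so pairing is likely. The difference in genes detected between SOL and PM ranged from 118.9 to 366.9 when 1 library was left out, also chosen after seeing the data. It passed only without SOL 5, in a permutation test that ignored the numbered pairs. Of 346 named-gene values under 29 settings, 345 kept direction and call, and 1 (ENSOARG00020005847 in PM against LL with the 10 FPKM filter) kept its log2 fold change of -8.09 but not its call, with a limma adjusted p of 0.26, the highest over its alternatives, of which the lowest was 7.7e-13. Median-ratio scaling changed the share of higher calls from 67.2% to 54.9% for SOL against LL, and gave 1260 higher and 1262 lower for SOL against PM, where 65.4% were higher as deposited. DESeq2 and total-count scaling were not run, since methods for counts were set aside for a table of FPKM. Size factors for counts entered only the voom fit on recovered reads. The alternatives for gene lists were not run because no list had members. Depth limits genes near 0.1 FPKM, which 1 read of a 1 kb gene nearly reaches.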

Other observations

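All tests in this part were chosen after the results were seen.

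The gene with the highest mean FPKM in SOL, singled out after its values were seen (recovered length 685 bp), stood at 37633 ± 8318 FPKM there, at 7571 ± 2819 in PM and at 2295 ± 2044 in LL (SD, n = 6 each). SOL exceeded LL by 4.51 (SE 0.53, limma adjusted p = 1.7e-06) and PM by 2.44 (limma adjusted p = 0.0024) on the log2 scale, and the PM against LL difference of 2.07 did not pass (limma adjusted p = 0.052). Its lowest value in both LL (337 FPKM) and PM (2113 FPKM) was in replicate 5.

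Genes with reads in all 6 libraries of one muscle and none in another were few: 29 in SOL and not LL, 6 in SOL and not PM, 10 in PM and not LL, 3 in PM and not SOL, 4 in LL and not SOL, and 0 in LL and not PM. With a mean of at least 10 reads required, these counts were 13 in SOL and not LL, 3 in SOL and not PM, 4 in PM and not LL, 3 in PM and not SOL, 3 in LL and not SOL, and 0 in LL and not PM. Absence from a single LL library is the less certain: 15.0% to 53.0% of genes with 5 to 20 reads in the other LL libraries had no read in an LL library. These shares are per library and do not gauge absence from all 6.

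PM may share part of the soleus difference from LL. Genes with a mean of at least 10 FPKM were called in SOL against LL on 3 replicate numbers and measured in the other 3, which gave 2 gene lists. Within same-numbered libraries, PM covered 21.2% ± 3.39 (SD, n = 6 replicate numbers) of the distance from LL to SOL, above 0 in 6 of 6. The numbers were not taken as pairs for LL, so means of 3 libraries were also used, with LL and PM relabelled in all 400 ways and the genes chosen again each time. The share was then 21.2%, and the real labels alone gave one as large (exact permutation p = 0.0025, two-sided, the smallest these relabellings can give).

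LL libraries standing apart from both other muscles for a technical reason would give such a share too. Genes called in SOL against PM, where LL entered only the estimate of the spread, gave 10.3% ± 4.90 (SD, n = 6 replicate numbers), above 0 in 6 of 6 (exact sign-flip permutation p = 0.031), and 9.45% ± 6.66 without the 10 FPKM minimum, above 0 in 5 of 6 (exact sign-flip permutation p = 0.062). With means of 3 libraries their share was 10.3% (exact permutation p = 0.11), and 9.45% without that minimum (exact permutation p = 0.14). A shared difference and a technical one cannot be told apart here, since only 1 of these 4 tests passed. That test treats the replicate numbers as pairs, which is likely for LL but did not meet the rule used.

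For each count of calls the libraries were also split in other ways. In each case the real split was the only 1 of 100 to give as many calls, the smallest share these splits can give. The real and highest other counts were 3915 and 544 for SOL against LL, and 2597 and 345 for SOL against PM. They were 229 and 48 for PM against LL, 2115 and 0 for genes setting SOL apart, and 3604 and 716 for genes differing among muscles. The other splits mix the muscles, so a difference between muscles adds to their spread and lowers their calls. The gaps therefore say no more than 1 of 100, and a technical difference that runs with muscle would pass as well. Among the 32 splits of SOL and PM that part every numbered pair, with the replicate block, the real one gave 3063 calls and the others 0. That is 1 of 32, the smallest share possible. The other splits again mix the muscles, so their lack of calls adds no further support.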
